A study of Mus musculus with 24 samples.

How the data were processed

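RNA of 24 cultures was labelled with biotin and measured on Affymetrix arrays, 1 array per culture. The cultures came from the subventricular zone of 6 mice, grown in a medium with serum and growth factors and then moved to 1 without either, and each mouse was sampled on days 0, 1, 2 and 4. Genotype, mouse and day were taken from the sample labels, so the samples form 8 groups of 3 arrays.

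The deposited table holds 28350 probe sets with 1 intensity per array, made by the authors by RMA (background correction, quantile normalisation and summary of probes) with Affymetrix Power Tools, and genome build mm9 is named per the submitters' processing notes, which give no versions. RMA ends on the log2 scale, but the deposited intensities are linear, with values from 3.48 to 30298, so log2 was taken. That the table was returned to the linear scale is inferred from the values. A companion table gives gene symbols and a cross-hybridisation code for each probe set, 1 for 25232 and 3 for 3118. Its codes are not explained there, and 1 was read as unique after the usage of the manufacturer. No measure of background was used here. Where the dimmer group had a mean below the mean lower quartile of its arrays (24.6 to 27.2 over the groups), called near the floor here, a difference is given as at least its value. The number of arrays limits the precision.

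Of the probe sets, 22232 carry exactly 1 symbol and were used. The 2980 with several symbols and the 3138 with none were left out of the comparisons and counted apart. Older symbols were updated on 2127 probe sets, and 25 symbols had been turned into dates by a spreadsheet. Of the 22232, 749 carry a symbol that is not in the RefSeq gene table of the reference. For the 576 genes with several probe sets, the probe set with the highest mean stood for the gene, which left 21072 genes.

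Models were fitted with limma 3.58.1 in R 4.3.3. Changes from day 0 within a genotype, and the difference between the genotypes in these changes, came from a fit of 8 group means to all 24 arrays. Genotypes were compared on each day in the same fit with the mouse as a random effect (consensus correlation 0.165), and over all days on 6 mouse means. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the 21072 genes of a comparison, moderated test, 2-sided), and 14 comparisons were made. SE is that of the log2 difference, and ± marks it unless SD is written. Figures were drawn with matplotlib 3.10.9.

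Each array of a mouse shares its mouse with 3 others, as the IDs in the labels show. Within a genotype, after the mean of each day was removed, arrays of the same mouse correlated across genes with a median r of 0.216 in wild-type cultures (lowest 0.0266, over 0.1 in 16 of 18 pairs) and 0.31 in Mll1-deleted ones (18 of 18). Arrays of different mice had a median of -0.124 and -0.142. The blocked fit, with the mouse as a fixed effect, was run for all time and difference-in-change comparisons.

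The 23 gene lists covered neurogenic transcription factors, neuroblasts, synapses, neural stem cells, astrocytes, oligodendrocytes, ependymal cells, microglia, endothelium with pericytes, extracellular matrix, proliferation, cyclin-dependent kinase inhibitors, targets of EGF and FGF, Notch, BMP and Sonic hedgehog signalling, cholesterol synthesis, amino acid and endoplasmic reticulum stress, p53 targets, interferon response, Hox genes, MLL complexes and sex-linked genes. Each was tested with camera in limma with a preset correlation of 0.01, adjusted over the 23 lists of a comparison. Of 151 calls, 7 held with an estimated correlation. These are the targets of EGF and FGF on day 1 in both genotypes and in the difference of changes, BMP targets on day 1 in Mll1-deleted cultures and in the difference, and interferon response in the difference on days 1 and 4. fry, also run, tests whether the genes of a list move one way on balance and does not compare them with other genes, and it called 90, but 0 for the genotypes on day 2, where camera called 14. No list past the camera threshold had a median, mean and test of different sign, and the lists that did had an adjusted p of 0.478 or more.

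Genes were named by a rule. It took the 8 largest increases and 8 largest decreases among called genes whose groups did not overlap (10% of genes by chance for 3 against 3), up to 4 members of each list with the smallest p, and always Kmt2a, Pou3f4, Dlx1, Dlx2 and Dlx5. Of these, genes whose call held under every alternative were preferred as examples after their values were seen, and a loss is given where one was not. The sample groups, tests of the comparisons, lists, named-gene rule and alternatives were fixed before the data were examined. The floor and some tests of explanations, named in the closing parts, were chosen after results were seen.

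The steps were tested on simulated data with 50 changed genes per fold among 21072. For day 1 against day 0, they recovered 8% of 1.25-fold, 34% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes with 4 false calls, or 10%, 42%, 96% and 100% with 5 false calls with the mouse as a block. Genotypes on day 0 gave 8%, 48%, 98% and 100% with 5 false calls, and the mean over days 28%, 94%, 100% and 100% with 14. The difference in change gave 0%, 16%, 70% and 100% with 2. The shifted list was called and 0 of the others were. Noise was simulated for each gene on its own, so this does not test list calls where genes vary together.

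Alternatives were to leave out the lowest 33.3% of genes by mean, to keep probe sets coded 1, to shift all arrays to the same median, to fit an intensity trend with a robust prior, to average the probe sets of a gene, and to leave out each mouse. The block or the random effect was added or removed, fits used only the 6 arrays compared, and for the mean over days each day was left out. A mouse left out leaves 2 arrays in its groups.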

Results

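Gene expression was measured on arrays in cultured neural stem cells from the subventricular zone of mice, a region that makes neurons after birth. Cultures of 3 wild-type mice (818, 862 and 870) and 3 mice labelled Mll1-deleted (489, 814 and 858) were sampled while dividing (day 0) and on days 1, 2 and 4 after the growth factors and serum were taken away. Mll1, whose current symbol is Kmt2a, encodes a histone H3 lysine 4 methyltransferase. Each of the 24 arrays holds 1 mouse on 1 day, which gives 8 groups of 3 arrays, and every group value has n = 3 mice. The median intensity of an array lay between 75.6 and 87.1 and its highest between 26748 and 30298. Within a group, arrays correlated with r between 0.984 and 0.996 across genes, and their number limits the precision of every value.

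Kmt2a itself (probe set 10592942) had a mean intensity of 388 in wild-type cultures on day 0, 483 on day 1, 592 on day 2 and 299 on day 4. In the Mll1-deleted cultures it was 540.5, 597, 631 and 383. The difference was 0.48 ± 0.13 (log2) on day 0 (adjusted p = 0.0175), a call lost without mouse 489 (adjusted p = 0.139), 814 (adjusted p = 0.124) or 870 (adjusted p = 0.0839), and with the 6 arrays of that day alone (adjusted p = 0.0784). The other days did not pass the test, with 0.31 ± 0.13 on day 1, 0.09 ± 0.13 on day 2 and 0.36 ± 0.13 on day 4. Another probe set, 10592938, which carries the symbol of Ttc36 as well and was left out of the comparisons, was at -0.03, -0.105, -0.06 and -0.16 on these 4 days. Which exons were removed and where the probes lie are not known, so these values do not check the deletion.

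The first principal component held 41.8% of the variance and followed the days of differentiation. Its mean in wild-type cultures went from -45.7 on day 0 to 9.52 on day 1, 27.2 on day 2 and 43.1 on day 4. Mll1-deleted cultures started at -47.3 and reached -16.1, 2.64 and 26.7. The SD among the 3 Mll1-deleted mice was 19.3 on day 1, against 2.97 among the wild-type mice.

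**Figure D1:**
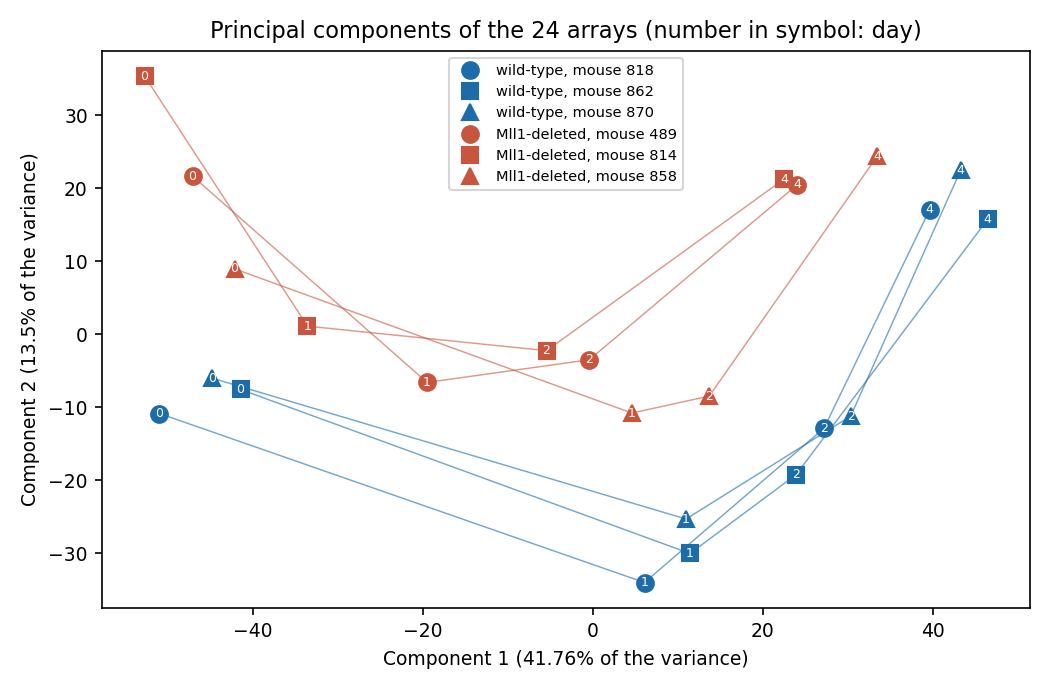
Principal component scores (no unit) of the 24 arrays, by day and genotype, each point 1 array. Mean scores on the first component, with 41.8% of the variance, rose with the day in both genotypes, and those of the Mll1-deleted cultures lay at -16.1, 2.64 and 26.7 on days 1, 2 and 4 against 9.52, 27.2 and 43.1 in wild-type cultures.

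The wild-type time course describes differentiation of normal cells. By day 1 Dcx, a microtubule protein of migrating neuroblasts, rose 10.1-fold (log2 3.33 ± 0.55, adjusted p = 9.2e-05), and Insm1, a transcription factor of neurogenic progenitors, rose as well (log2 2.51 ± 0.17, adjusted p = 1.3e-09). Among the homeobox factors of interneuron progenitors, Dlx1 rose by 2.59 ± 0.40, Dlx2 by 2.30 ± 0.30 and Dlx5 by 2.29 ± 0.43 on the log2 scale. Pou3f4, also called Brn4 and named in the series title, encodes a POU-domain transcription factor and rose by 1.07 ± 0.19. In all, 17 of 29 neurogenic transcription factors rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 2.8e-07, or adjusted p = 0.197 with an estimated correlation). Among neuroblast markers 9 of 26 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.00512, or adjusted p = 0.627 with an estimated correlation).

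Targets of growth factor signalling dropped on the same day. The feedback inhibitor Spry4 (-3.64 ± 0.20), the immediate early gene Ier3 (-4.19 ± 0.15) and Ccnd1, the cyclin that drives entry into the cell cycle (-3.57 ± 0.28), fell together with most of their list, 14 of 20 members, the same 14 adjusted over the list alone (adjusted p = 4.8e-14). That call held with an estimated correlation (adjusted p = 0.016). Of 28 proliferation genes 24 fell (27 adjusted over the list alone), such as Ccnb2 (-1.80 ± 0.26) and Cdc20 (-1.38 ± 0.23), both of mitosis (adjusted p = 6.2e-11, or adjusted p = 0.517 with an estimated correlation). Cholesterol synthesis went down in 10 of 21 genes (15 adjusted over the list alone, adjusted p = 1.1e-05, or adjusted p = 0.517 with an estimated correlation), among them the sterol-regulated gene Insig1 (-1.35 ± 0.15). In contrast, 10 of 20 astrocyte markers rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 1.7e-05, or adjusted p = 0.517 with an estimated correlation), with the gap junction protein Gja1 at 1.48 ± 0.11. Interferon-response genes rose in 9 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 1.5e-04, or adjusted p = 0.1 with an estimated correlation), Ifit1 by at least 1.20 ± 0.21. Over all 21072 genes, limma called 5363 changed, 2455 up and 2908 down, and 3554 without mouse 862.

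On day 2 Dcx in wild-type cultures stood 63.8-fold above day 0 (SE 0.55 on the log2 scale, adjusted p = 3.1e-08). Dlx5 was up by 4.23 ± 0.43, Dlx1 by 3.29 ± 0.40, Dlx2 by 2.42 ± 0.30 and Pou3f4 by 1.60 ± 0.19. St18, a zinc finger factor of neurons, rose by 2.51 ± 0.22. Neurogenic transcription factors rose in 21 of 29 cases and fell in 1 (21 and 1 adjusted over the list alone, adjusted p = 1.5e-10, or adjusted p = 0.0933 with an estimated correlation), and neuroblast markers in 19 of 26, with 2 lower (19 and 2 adjusted over the list alone, adjusted p = 4.9e-08, or adjusted p = 0.223 with an estimated correlation). Synaptic genes rose in 10 of 22 cases and fell in 3, the same numbers adjusted over the list alone (adjusted p = 0.0247, or adjusted p = 0.33 with an estimated correlation), but without mouse 818 the list missed the threshold (adjusted p = 0.0554). The Notch target Hes1, which holds progenitors undifferentiated, fell (-2.53 ± 0.21), as did 5 of 13 Notch genes against 2 that rose (9 and 2 adjusted over the list alone, adjusted p = 0.0166, or adjusted p = 0.33 with an estimated correlation), a list call lost without mouse 818 (adjusted p = 0.0527). Proliferation was lower in 25 of 28 genes (28 adjusted over the list alone, adjusted p = 9.6e-11, or adjusted p = 0.33 with an estimated correlation). The count for day 2 was 7095 genes, 3297 up and 3798 down. The share that rose was 46.5%, or 33.6% after the arrays were shifted to the same median.

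On day 4 all 28 proliferation genes had fallen in wild-type cultures, with the same 28 adjusted over the list alone (adjusted p = 1.7e-25, or adjusted p = 0.118 with an estimated correlation). Mki67, a protein of cycling cells, was at log2 -4.55 ± 0.31, adjusted p = 3.0e-10, and Foxm1, a factor of mitotic transcription, at -3.01 ± 0.21. All 11 ependymal genes rose, again 11 adjusted over the list alone (adjusted p = 3.2e-10, or adjusted p = 0.0901 with an estimated correlation), including Rsph1 (2.81 ± 0.20), a radial spoke gene of motile cilia. Rsph4a, another such gene that is not in the list, rose by at least 4.13 ± 0.27. Dcx stayed above day 0 by 5.31 ± 0.55, Dlx1 by 2.10 ± 0.40, Dlx5 by 3.08 ± 0.43 and Pou3f4 by 0.82 ± 0.19. Dlx2 was at 0.99 ± 0.30 (adjusted p = 0.0126), a call lost without mouse 818 (adjusted p = 0.101), 862 or 870 (adjusted p = 0.0604 for both). Neural stem cell markers fell in 11 of 21 cases and rose in 4, with the same numbers adjusted over the list alone (adjusted p = 0.0175, or adjusted p = 0.423 with an estimated correlation).

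Of 15 measured members of the MLL and H3K4 methyltransferase complexes 9 fell by day 4 (10 adjusted over the list alone, adjusted p = 0.00378, or adjusted p = 0.352 with an estimated correlation), among them the methyltransferase Kmt2b (-0.82 ± 0.12) and the cofactor Hcfc1 (-0.96 ± 0.14). The lists of microglia (adjusted p = 0.312), of endothelium and pericytes (0.888) and of sex-linked genes (0.901) did not pass on day 4. Cyclin-dependent kinase inhibitors were at adjusted p = 0.948 with a median of 0.10 (log2), a mean of -0.13 and a test that pointed down. In total 7905 genes changed, 3604 up and 4301 down, and the share that rose was 45.6%, or 34.1% after the shift.

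The Mll1-deleted time course asks how cultures labelled Mll1-deleted change in the same medium. On day 1 the growth factor targets fell here too, with Spry4 at -2.01 ± 0.20 and Ier3 at -1.92 ± 0.15 on the log2 scale. Of that list 13 of 20 fell and 2 rose (16 and 2 adjusted over the list alone, adjusted p = 4.6e-09), a call that held with an estimated correlation (adjusted p = 0.0462). BMP targets fell in 8 of 12 cases, the same 8 adjusted over the list alone (adjusted p = 2.3e-07, and adjusted p = 0.019 with an estimated correlation), led by Id1, an inhibitor of differentiation (-2.18 ± 0.34), and by the pseudoreceptor Bambi (-1.06 ± 0.15). Neurogenic factors rose in 9 of 29 cases (11 adjusted over the list alone, adjusted p = 2.0e-06, or adjusted p = 0.284 with an estimated correlation), with Insm1 at log2 1.30 ± 0.17, adjusted p = 2.7e-05, Sox4 at 1.49 ± 0.20 and Pou3f4 at 0.78 ± 0.19. Dlx1 rose by 1.92 ± 0.40 (1.24 without mouse 858), while Dlx2 at 1.21 ± 0.30 lost its call without that mouse (0.70, adjusted p = 0.104) and in the 6 arrays of these days alone (adjusted p = 0.0987), and Dlx5 at 0.14 ± 0.43 did not pass (adjusted p = 0.922). The proliferation list was lower by a median of -0.45, with 3 of 28 members past the test, also 3 adjusted over the list alone (adjusted p = 3.9e-05, or adjusted p = 0.738 with an estimated correlation). Without mouse 858 that median was -0.04 and the test pointed up (adjusted p = 0.86), and without mouse 814 it was -0.797. The count was 2610 genes, 1236 up and 1374 down, 1057 without mouse 489 and 679 from the 6 arrays of these days alone.

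By day 2 Dcx had risen by at least 3.53 ± 0.55 in Mll1-deleted cultures and Dlx5 by 2.10 ± 0.43. Myt1, a zinc finger factor of neurons and oligodendrocyte precursors, was up by 2.95 ± 0.36. Neurogenic factors rose in 11 of 29 cases (15 up and 1 down adjusted over the list alone, adjusted p = 1.2e-07, or adjusted p = 0.162 with an estimated correlation). Astrocyte markers such as Apoe, a lipid carrier (2.44 ± 0.29), and Clu (0.88 ± 0.12) rose in 12 of 20 cases (13 up and 1 down adjusted over the list alone, adjusted p = 1.6e-06, or adjusted p = 0.439 with an estimated correlation). Proliferation genes fell in 21 of 28 cases (24 adjusted over the list alone, adjusted p = 1.8e-09, or adjusted p = 0.439 with an estimated correlation), and so did 8 of 18 genes of the extracellular matrix (9 adjusted over the list alone, adjusted p = 0.00154, or adjusted p = 0.572 with an estimated correlation), with fibronectin, encoded by Fn1, at -1.97 ± 0.42. The test called 4916 genes, 1983 up and 2933 down, with 3217 left without mouse 489 and 3235 without mouse 814.

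By day 4 genes of the oligodendrocyte lineage, the myelinating cells, had risen in Mll1-deleted cultures. Bcas1, a gene of newly formed oligodendrocytes, rose at least 18.4-fold (log2 4.20 ± 0.40, adjusted p = 9.6e-08), from an intensity of 21.71 near the floor, Gpr17, a receptor of committed precursors, by 4.56 ± 0.52, and Ugt8a, a myelin lipid enzyme, by 2.62 ± 0.32. Of that list 13 of 19 rose (14 adjusted over the list alone, adjusted p = 3.9e-08, or adjusted p = 0.183 with an estimated correlation), and its median relative to wild-type day 0 was 2.41 in mouse 858, 0.947 in mouse 489 and 0.466 in mouse 814. Ependymal genes rose in 10 of 11 cases (11 adjusted over the list alone, adjusted p = 1.5e-10, or adjusted p = 0.099 with an estimated correlation) and astrocyte markers in 14 of 20, with 2 lower (16 and 2 adjusted over the list alone, adjusted p = 9.7e-07, or adjusted p = 0.413 with an estimated correlation). The complement genes C3 (4.77 ± 0.34) and C4b (4.44 ± 0.29) were among the largest increases. The Hox list was called higher, a call lost without mouse 814 (median 0.191, adjusted p = 0.0537) and with an estimated correlation. Dcx was up by at least 4.97 ± 0.55, with 14 of 26 neuroblast markers higher and 1 lower, the same numbers adjusted over the list alone (adjusted p = 4.0e-04, or adjusted p = 0.461 with an estimated correlation). All 28 proliferation genes had fallen, 28 adjusted over the list alone (adjusted p = 6.8e-24, or adjusted p = 0.183 with an estimated correlation), with Foxm1 at -2.26 ± 0.21. In all 6231 genes changed, 2922 up and 3309 down, and 4024 without mouse 489. The share that rose was 46.9%, or 34.3% after the shift.

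**Figure D2:**
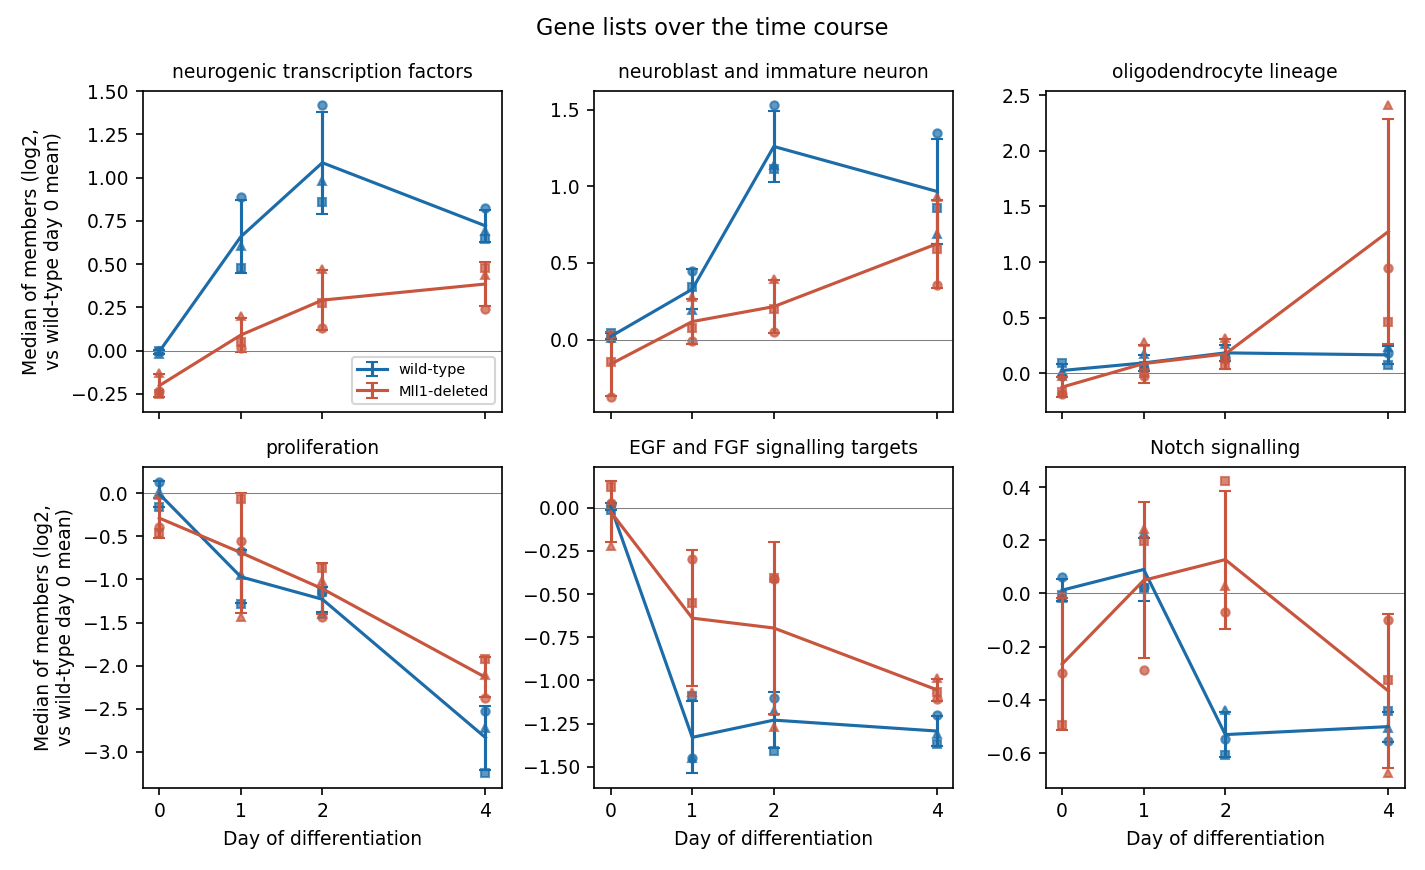
Median of the members of 6 gene lists (log2, relative to the wild-type mean on day 0) against the day, with 1 point per mouse and lines and bars for the mean and SD of 3 mice. The oligodendrocyte list reached a mean of 1.27 in Mll1-deleted cultures on day 4, with an SD of 1.01 among the 3 mice, against 0.17 in wild-type cultures.

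Across the 21072 genes, which are not independent replicates, the changes of the genotypes correlated with r = 0.68 and rho = 0.588 on day 1, r = 0.716 and rho = 0.658 on day 2, and r = 0.774 and rho = 0.685 on day 4. The slope of Mll1-deleted on wild-type changes was 0.647, 0.729 and 0.798 by total least squares, which is not the slope of an ordinary regression. Without mouse 858 the day 4 correlation was 0.701. On day 4, 1863 genes rose and 2486 fell in both genotypes, and 87 went opposite ways, where independent calls would give 500, 675 and 1160.

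The comparison of genotypes before differentiation asks whether dividing cells already differ. On day 0 Pou3f4 was lower in Mll1-deleted cultures (log2 -1.36 ± 0.19, adjusted p = 4.1e-05, an intensity of 127 against 325), as were the related Pou3f2 (-1.05 ± 0.17) and the progenitor factor Pax6, at -0.60 ± 0.11 by 1 probe set and -0.33 by the other. Dlx1 at -1.14 ± 0.38 (adjusted p = 0.0569), Dlx2 at -0.48 ± 0.29 and Dlx5 at -0.12 ± 0.39 did not pass. Of 29 neurogenic factors 6 were lower (9 lower and 1 higher adjusted over the list alone, adjusted p = 0.00137, or adjusted p = 0.172 with an estimated correlation). Matrix genes were higher in 9 of 18 cases (12 adjusted over the list alone, adjusted p = 8.7e-07, or adjusted p = 0.482 with an estimated correlation). Among them were the secreted Thbs1 (log2 3.81 ± 0.35, adjusted p = 2.5e-07), Ccn1 (1.94 ± 0.21) and Ccn2 (2.05 ± 0.31), which act at the cell surface. The hedgehog receptor Ptch1 (1.43 ± 0.21) and the effector Gli3 (0.98 ± 0.18) were higher with 5 of 11 genes of that pathway, the same number adjusted over the list alone (adjusted p = 2.1e-04, or adjusted p = 0.135 with an estimated correlation). BMP targets were higher in 4 of 12 cases (6 adjusted over the list alone, adjusted p = 9.2e-08, or adjusted p = 0.105 with an estimated correlation), for example Smad6, an inhibitor of the pathway (0.83 ± 0.15), and p53 targets in 4 of 14 (7 adjusted over the list alone, adjusted p = 2.6e-04, or adjusted p = 0.7 with an estimated correlation). Astrocyte markers were lower in 8 of 20 cases and higher in 1 (10 and 3 adjusted over the list alone, adjusted p = 0.0039, or adjusted p = 0.802 with an estimated correlation), with Aldh1l1 at -1.78 ± 0.29. The interferon list was called higher (median 0.214), a call lost without mouse 489 (adjusted p = 0.0988). Proliferation was called lower, a call lost without mouse 818 (adjusted p = 0.0505). Neither call held with an estimated correlation. Without mouse 814 the astrocyte median went from -0.521 to -0.196 (adjusted p = 0.0382), that of the matrix from 0.984 to 0.58, of p53 targets from 0.365 to 0.241 and of hedgehog genes from 0.315 to 0.506, and without mouse 489 that of neurogenic factors from -0.117 to -0.203. limma called 2132 genes, 1140 higher and 992 lower, and after the shift to the same median 1027 were higher and 1134 lower. With the 6 arrays of that day alone it was 1315, and it was 1199 without mouse 489, 1181 without 814, 1404 without 862 and 1218 without 870.

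On day 1 Pou3f4 was lower in the Mll1-deleted cultures, at log2 -1.65 ± 0.19, adjusted p = 7.1e-06, as were Dlx5 at log2 -2.27 ± 0.39, adjusted p = 5.3e-04, and Dlx2 at log2 -1.58 ± 0.29, adjusted p = 0.00114. Dlx1 (-1.81 ± 0.38, adjusted p = 0.00305) had an adjusted p of 0.05 without mouse 818. Igfbpl1, expressed in neuroblasts, was at -1.77 ± 0.14. Neurogenic factors were lower in 11 of 29 cases and higher in 1 (15 and 2 adjusted over the list alone, adjusted p = 4.3e-09, or adjusted p = 0.319 with an estimated correlation). Growth factor targets were higher in 8 of 20 cases (10 adjusted over the list alone, adjusted p = 5.2e-10, or adjusted p = 0.316 with an estimated correlation), Ccnd1 by 2.06 ± 0.27 and Phlda1 by 1.05 ± 0.15, and without mouse 814 the median of the list went from 0.59 to 0.355. The glial lineage factors Olig1 (1.63 ± 0.18) and Olig2 (1.12 ± 0.16) were higher, while 8 of 20 astrocyte markers were lower (12 adjusted over the list alone, adjusted p = 1.4e-09, or adjusted p = 0.319 with an estimated correlation), with Gja1 at -0.73 ± 0.11. The count was 1570 genes, 761 higher and 809 lower, and 809 from the 6 arrays of that day. It was 830 without mouse 489, 835 without 814, 939 without 818, 2758 without 858, 1003 without 862 and 934 without 870.

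On day 2 more neurogenic factors were lower in Mll1-deleted cultures than on the other days. Pou3f4 was at log2 -2.09 ± 0.19, adjusted p = 3.8e-07, Dcx at log2 -2.99 ± 0.53, adjusted p = 7.2e-04 and Dlx5 at log2 -2.24 ± 0.39, adjusted p = 5.7e-04. Dlx1 was at -1.64 ± 0.38, and without mouse 818 its adjusted p was 0.0724. Dlx2 (-1.05 ± 0.29, adjusted p = 0.0258) lost its call without mouse 489 (adjusted p = 0.198), 814 (0.0522), 818 (0.179), 862 (0.066) or 870 (0.0786). Of 29 neurogenic factors 16 were lower (18 adjusted over the list alone, adjusted p = 5.8e-10, or adjusted p = 0.365 with an estimated correlation), with St18 at -2.08 ± 0.23 on the log2 scale. Neuroblast markers were lower in 15 of 26 cases and higher in 1 (17 and 1 adjusted over the list alone, adjusted p = 5.6e-09, or adjusted p = 0.365 with an estimated correlation). They include Gad1, the enzyme that makes the transmitter GABA (-1.56 ± 0.20). Notch genes were higher in 8 of 13 cases, the same 8 adjusted over the list alone (adjusted p = 1.7e-07, or adjusted p = 0.365 with an estimated correlation), with the receptor Notch3 at 0.83 ± 0.16 and the ligand Dll1 at 1.21 ± 0.19. Stem cell markers were higher in 7 of 21 and lower in 2 (8 and 3 adjusted over the list alone, adjusted p = 4.1e-04, or adjusted p = 0.535 with an estimated correlation), the filament gene Nes by 1.76 ± 0.19. Ependymal genes were lower in 4 of 11 cases (9 adjusted over the list alone, adjusted p = 1.9e-04, or adjusted p = 0.555 with an estimated correlation). The Hox list was called lower (median -0.111), a call lost without mouse 489 (adjusted p = 0.0827), 814 (0.117) or 870 (0.298) and with an estimated correlation. Members such as Hoxa3 and Hoxc6 were near the floor in both genotypes. In all 1842 genes differed, 845 higher and 997 lower, and after the shift 1052 were higher and 836 lower. The count was 911 without mouse 489, 1126 without 814, 935 without 818 and 1124 without 870.

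**Figure D3:**
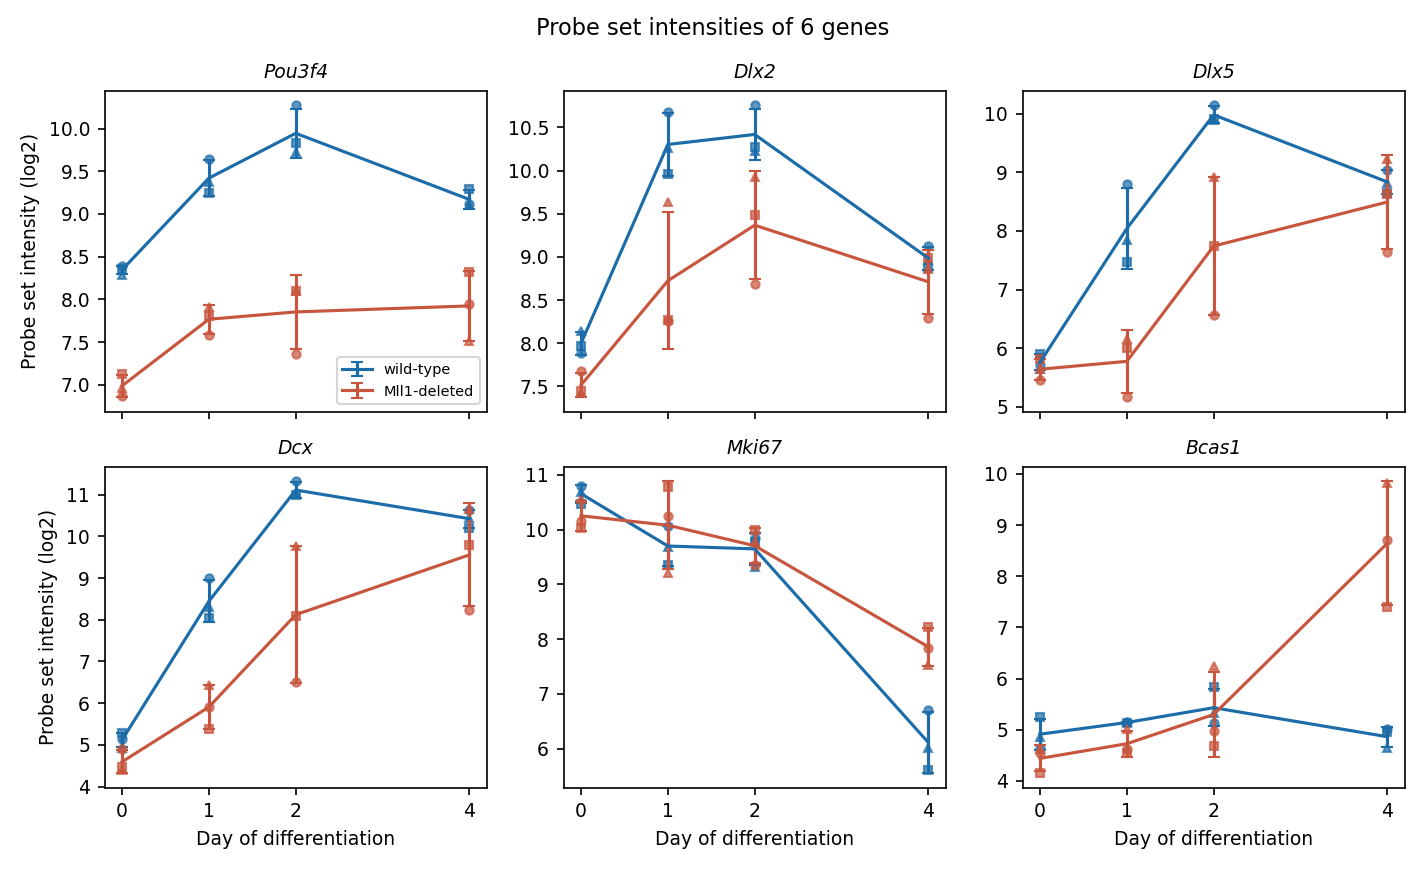
Log2 intensity of 6 genes against the day, with 1 point per mouse and lines and bars for the mean and SD of 3 mice of each genotype. Pou3f4 was lower in the Mll1-deleted cultures on all 4 days, by 2.56-fold, 3.14-fold, 4.26-fold and 2.37-fold, and Bcas1 was higher on day 4 by 3.78 (log2).

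On day 4 Bcas1 was higher in Mll1-deleted cultures (log2 3.78 ± 0.37, adjusted p = 1.0e-06), Enpp6, of early myelinating cells, by at least 2.94 ± 0.41 and Olig2 by 1.56 ± 0.16. Oligodendrocyte genes were higher in 12 of 19 cases (14 adjusted over the list alone, adjusted p = 9.4e-15, or adjusted p = 0.233 with an estimated correlation). Cholesterol synthesis was higher in 16 of 21 genes (20 adjusted over the list alone, adjusted p = 1.3e-23, or adjusted p = 0.104 with an estimated correlation), among them Fdft1 (1.38 ± 0.15). The proliferation list was higher in 9 of 28 genes (19 adjusted over the list alone, adjusted p = 1.5e-16, or adjusted p = 0.349 with an estimated correlation), Mki67 by 1.75 ± 0.31. Notch genes were higher in 5 of 13 cases (8 higher and 1 lower adjusted over the list alone, adjusted p = 4.4e-05, or adjusted p = 0.104 with an estimated correlation). Pou3f4 was lower here as well (2.37-fold, SE 0.19 on the log2 scale, adjusted p = 2.0e-04), with 6 of 29 neurogenic factors, the same 6 adjusted over the list alone (adjusted p = 1.3e-04, or adjusted p = 0.233 with an estimated correlation), and a list median of -0.274 that was -0.119 without mouse 489. Dlx1 (-0.73 ± 0.38), Dlx2 (-0.27 ± 0.29) and Dlx5 (-0.34 ± 0.39) did not pass. Interferon-response genes were lower in 6 of 16, also 6 adjusted over the list alone (adjusted p = 2.9e-04, or adjusted p = 0.233 with an estimated correlation), as in Rtp4 (-0.79 ± 0.16). Amino acid and endoplasmic reticulum stress genes were lower in 1 of 13 (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0123, or adjusted p = 0.464 with an estimated correlation), a list call lost without mouse 818 (adjusted p = 0.0728) or 858 (adjusted p = 0.0547), and its median of -0.179 was -0.274 without mouse 862. The count was 1361 genes, 786 higher and 575 lower, and 773 from the 6 arrays of that day. It was 760 without mouse 489, 907 without 814, 809 without 862 and 675 without 870.

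Averaged over the 4 days, 1 value per mouse, Pou3f4 was lower in Mll1-deleted cultures (log2 -1.59 ± 0.11, adjusted p = 2.1e-04), and so were Igfbpl1 (-1.20 ± 0.08) and Gad2, another GABA-making enzyme (-1.80 ± 0.23). The cell cycle inhibitor Cdkn1b was at -0.71 ± 0.07 by 1 probe set and -0.69 by the other. Higher were Nes (1.03 ± 0.11), Olig1 (0.97 ± 0.09), Olig2 (0.80 ± 0.10) and Ptch1 (0.85 ± 0.13). Neurogenic factors were lower in 14 of 29 cases (19 lower and 1 higher adjusted over the list alone, adjusted p = 2.3e-10, or adjusted p = 0.382 with an estimated correlation), and cholesterol genes higher in 9 of 21 (14 adjusted over the list alone, adjusted p = 2.3e-10, or adjusted p = 0.382 with an estimated correlation). The test on 6 mouse means called 1539 genes, 757 higher and 782 lower, and the fit to all 24 arrays with the mouse as a random effect called 2812. It was 821 without mouse 489, 948 without 814, 856 without 818, 2592 without 858, 693 without 862 and 668 without 870. By day, 4512 genes were called on 1 or more days, 191 on all 4 (101 higher and 82 lower in the Mll1-deleted cultures throughout) and 152 on several days with opposite signs.

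The difference between the changes of the genotypes was tested directly. On day 1 growth factor targets had dropped less in Mll1-deleted cultures, with a difference of log2 2.27 ± 0.22, adjusted p = 8.2e-06 for Ier3 and 1.63 ± 0.28 for Spry4. Both had started lower on day 0, at -1.57 ± 0.15 and -0.95 ± 0.20. The difference was positive in 10 of 20 members (11 positive and 1 negative adjusted over the list alone, adjusted p = 1.2e-10, and adjusted p = 0.0426 with an estimated correlation). Olig1 (2.15 ± 0.25) and Olig2 (1.94 ± 0.23) changed differently, and both had fallen in wild-type cultures, Olig1 at -1.75 ± 0.18 and Olig2 at -1.73 ± 0.17. BMP targets differed the other way in 3 of 12 cases (5 adjusted over the list alone, adjusted p = 8.8e-05, and adjusted p = 0.0426 with an estimated correlation), as for Id4 (-1.90 ± 0.29). This list had started higher in Mll1-deleted cultures. Its mean over mice, relative to wild-type day 0, was 0.503 against -0.007 in wild-type cultures on day 0. On day 1 it was -0.173 against -0.118. Pou3f4 did not differ in its change past the test (-0.29 ± 0.28, adjusted p = 0.739). The count was 513 genes, 270 positive and 243 negative, and 1031 with the mouse as a block. Leaving out a mouse gave 165 (489), 193 (814), 179 (818), 1451 (858), 219 (862) and 159 (870).

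From day 0 to day 2 changes differed for the microtubule genes Stmn2 (log2 -3.89 ± 0.59, adjusted p = 3.3e-04) and Tubb3 (-3.02 ± 0.48) and for St18 (-2.14 ± 0.31). Stmn2 rose in wild-type cultures (1.84) and fell in Mll1-deleted ones (-2.04), where it had been higher on day 0 (2.72 ± 0.39). Neuroblast markers differed downward in 10 of 26 cases and upward in 1 (16 and 1 adjusted over the list alone, adjusted p = 2.8e-07, or adjusted p = 0.211 with an estimated correlation). Notch genes differed upward in 7 of 13 (7 up and 1 down adjusted over the list alone, adjusted p = 2.8e-07, or adjusted p = 0.0558 with an estimated correlation), Dll1 by 1.99 ± 0.28. Egfr, the EGF receptor, was at 2.42 ± 0.32 and Olig2 at 2.14 ± 0.23. Dlx5 (-2.12 ± 0.60, adjusted p = 0.0442) lost its call without mouse 489 (adjusted p = 0.0802), 814 (0.198), 818 (0.17), 862 (0.108) or 870 (0.189) and with an intensity trend in the variance (0.0728). In all 1012 genes differed, 460 up and 552 down, and 1860 with the mouse as a block. Of them 45.5% were up, or 61% after the shift to the same median. Leaving out a mouse gave 390 (489), 488 (814), 446 (818), 1690 (858), 644 (862) and 429 (870).

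From day 0 to day 4 the oligodendrocyte genes rose more in Mll1-deleted cultures, where Bcas1 differed by at least log2 4.25 ± 0.57, adjusted p = 1.1e-04 and Ugt8a by 2.74 ± 0.45, with 11 of 19 members past the test (13 adjusted over the list alone, adjusted p = 7.3e-13, or adjusted p = 0.0831 with an estimated correlation). Cholesterol genes differed upward in 10 of 21 cases (15 adjusted over the list alone, adjusted p = 1.0e-11, or adjusted p = 0.129 with an estimated correlation), as in Hmgcs1 (1.59 ± 0.28), and proliferation genes in 5 of 28 (21 adjusted over the list alone, adjusted p = 6.6e-11, or adjusted p = 0.423 with an estimated correlation). Interferon-response genes differed downward in 6 of 16 (9 adjusted over the list alone, adjusted p = 2.7e-06, and adjusted p = 0.049 with an estimated correlation), with Bst2 at -1.01 ± 0.20. The interferon and proliferation lists had started apart, by their means over mice relative to wild-type day 0. For interferon, Mll1-deleted cultures were at 0.236 against -0.011 in wild-type cultures on day 0, and 0.373 against 0.62 on day 4. For proliferation they were at -0.287 against -0.00687 on day 0, and -2.14 against -2.84 on day 4. Thbs1, high on day 0, was at -4.08 ± 0.57. The change of Pou3f4 did not differ past the test (0.11 ± 0.28, adjusted p = 0.892). The count was 1229 genes, 689 up and 540 down, and 2148 with the mouse as a block. Without 1 mouse it was 421 (489), 583 (814), 685 (818), 2014 (858), 534 (862) or 424 (870).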

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

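Chosen only after the result was seen were the tests of array scaling and of a single Mll1-deleted mouse for both patterns weighed here and that of precursor markers on day 0, whose bound was also changed after its value was known; the other tests here were planned.

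The changes of the genotypes differed, by the test of the difference itself, at 513 genes on day 1, 1012 on day 2 and 1229 on day 4. For each count, 10 splits of the 6 mice are too few for a share under 0.05, 1 of them (the real split) gave as many genes, and the highest of the others was 0. On day 1 the median difference of change (log2) was 0.99 for targets of EGF and FGF, -0.397 for BMP targets and -0.365 for interferon response. It was 0.479 for proliferation, 0.318 for Notch, 0.309 for cholesterol synthesis, 0.158 for the oligodendrocyte lineage, -0.202 for neurogenic factors and -0.257 for ependymal cells. These last 6 lists had adjusted p = 0.567 with an estimated correlation. The BMP and interferon lists had started higher in Mll1-deleted cultures on day 0, and the proliferation list lower. Without mouse 818 the neurogenic (adjusted p = 0.135), oligodendrocyte (0.0526) and Notch (0.136) calls were lost, and without mouse 814 that of proliferation (median 0.03, adjusted p = 0.253). Medians moved by over 1.5 times to 1.0 (proliferation) and 0.536 (cholesterol) without mouse 858, and to 0.157 (cholesterol), 0.21 (Notch) and -0.413 (ependymal) without 814. Without mouse 862 the ependymal median was -0.519, and the oligodendrocyte median was 0.286, 0.00607 and 0.0968 without 814, 858 and 862.

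On day 2 the median difference of change was -0.892 for neuroblasts, -0.558 for neurogenic factors (-0.342 without mouse 489), 0.992 for Notch, 0.588 for targets of EGF and FGF, -0.419 for interferon response, -0.399 for BMP targets and -0.503 for ependymal cells. With an estimated correlation these 7 had adjusted p = 0.211, 0.241, 0.0558, 0.179, 0.0558, 0.111 and 0.337 in that order. It was 0.362 for the oligodendrocyte lineage (0.213 and 0.157 without mouse 814 and 858), 0.0943 for neural stem cells, 0.35 for proliferation, -0.285 for synapses and -0.396 for the matrix, with adjusted p = 0.483, 0.337, 0.879, 0.337 and 0.755 with an estimated correlation. The neural stem cell median was 0.226, 0.011, 0.305, 0.38 and 0.189 without mouse 489, 814, 858, 862 and 870, and without 818 its call was lost (adjusted p = 0.063). Proliferation lost its call without mouse 814 (0.115, adjusted p = 0.265), 818 (adjusted p = 0.0588) and 870 (0.221, adjusted p = 0.0899), and synapses without 489 (adjusted p = 0.0554), 814 (adjusted p = 0.0613) and 818 (adjusted p = 0.0567). The matrix lost its call without 818 (adjusted p = 0.0579) and 870 (adjusted p = 0.0899), and its median was -0.242 without 858. Dlx5 differed by -2.12 on day 2, a call lost without mouse 489 (adjusted p = 0.0802), 814 (adjusted p = 0.198), 818 (adjusted p = 0.17), 862 (adjusted p = 0.108) and 870 (adjusted p = 0.189) and with an intensity trend (adjusted p = 0.0728).

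On day 4 it was 1.29 for the oligodendrocyte lineage, 0.898 for cholesterol synthesis, 1.05 for proliferation, 0.741 for Notch, -0.423 for BMP targets (-0.688 without mouse 818), -0.869 for the matrix (-0.542 without mouse 814), 0.715 for astrocytes (0.35 without mouse 814) and -0.314 for p53 targets. With an estimated correlation these 8 had adjusted p = 0.0831, 0.129, 0.423, 0.116, 0.1, 0.463, 0.508 and 0.463 in that order. Interferon response was at -0.513. Ependymal cells were at -0.209 (adjusted p = 0.536 with an estimated correlation), a call lost without mouse 489 (-0.02, adjusted p = 0.246) and 818 (-0.00915, adjusted p = 0.222), with a median of -0.379 without 858 and -0.347 without 870. Among the 6118 probe sets with several symbols or none, which the comparisons do not use, 31 (0.507%) differed between the genotypes in the mean over days, 9 higher and 22 lower.

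Neuroblast and neurogenic genes were lower in Mll1-deleted cultures on day 2, in 15 of 26 and 16 of 29 members. For the genotypes on that day fry called 0 lists, as did camera with an estimated correlation. A constant shift of whole arrays is argued against, since the median of the 55 members stayed at -0.841 after it was removed. What was removed on that day was only -0.0444 in the median over all genes, and scaling that varies with intensity was not tested. A single Mll1-deleted mouse is argued against too, since the median of the members stayed at -0.749 or further below 0 with any 1 left out. For slower progress along the wild-type course as the whole difference, the planned test does not decide. All 3 day 2 arrays lay above or all below the 12 wild-type arrays at 4.82% of genes (1016). The 0.44% set as chance holds for exchangeable arrays. The wild-type arrays are 3 mice on 4 days, so they are not exchangeable, and states between the sampled days were not seen. The genotypes already differed at 2132 genes on day 0, and at 1181 or more with any 1 mouse left out. Growth factors and serum had not yet been taken away, so slower progress after that step cannot account for these genes. They argue against it as the whole difference. For the lower members themselves slower progress cannot be told apart from another effect of the genotype, as 67.7% of them (21 of 31, Wilson 95% interval 50.1 to 81.4%) had day 2 means inside the range of wild-type day means. Another 10 lay below every wild-type day mean, among them Calb2, which was near the floor and decides nothing, and Pou3f4, Pax6 and Gad2, which may depend on Mll1 at all stages, a hypothesis that needs binding data.

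Oligodendrocyte genes were higher in Mll1-deleted cultures on day 4, in 12 of 19 members, a list call that did not hold with an estimated correlation. A constant shift of whole arrays, 0.0152 in the median over all genes on that day, is argued against by a median of 1.08 after it was removed. Scaling that varies with intensity was not tested here either. A single mouse is argued against by a median of 0.812 at the lowest with any 1 Mll1-deleted mouse left out. More precursors already present on day 0 stay open, because 5 precursor markers moved apart there, with a median of -0.116, which the first bound, at or below 0 and blind to their spread, had counted against it. Olig2 was lower at -0.81, while Olig1 at -0.52 (adjusted p = 0.0769), Sox10 at -0.12, Pdgfra at 0.92 (adjusted p = 0.0641) and Cspg4 at 0.29 did not pass the test. A turn of Mll1-deleted progenitors toward the oligodendrocyte lineage is a candidate explanation that was not tested apart from this.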

How the results depend on the processing

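All alternatives here were planned, and none was chosen after a result was seen. Leaving out genes with the lowest means, keeping probe sets coded 1, shifting arrays to the same median, an intensity trend and averaging probe sets left all 14 gene counts within 1.5 times. Among 1061 named calls, the shift ended 23, the trend 18 and averaging 2. The mouse as a block moved the counts of difference in change to 1031 on day 1, 1860 on day 2 and 2148 on day 4. It ended no call of a list or named gene, with 94 lists and 715 genes called in both fits, and 4 named genes gained one. Fits to only the 6 arrays compared gave 679 genes for Mll1-deleted day 1, and 1315, 809 and 773 for the genotypes on days 0, 1 and 4, and they ended 54 named calls over time, where fewer arrays estimate the variance, and 69 between genotypes, where the random effect was dropped as well. Dropping it alone in the fit of 24 arrays ended 15. The fit of 24 arrays with the mouse as a random effect gave 2812 for the mean over days, where arrays and not mice are counted. An estimated correlation kept 7 of the 151 list calls and fry, which asks another question, called 90; the block gave 99 in 9 comparisons. Between genotypes fry called 3, 4, 0 and 2 lists on days 0, 1, 2 and 4 and 1 for the mean over days, where camera called 8, 11, 14, 9 and 15.

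Leaving out each mouse, which leaves fewer arrays, gave 3554 to 5710 genes for wild-type day 1, 5114 to 7443 for day 2 and 6096 to 8164 for day 4. For Mll1-deleted cultures it gave 1057 to 2427, 3217 to 4826 and 4024 to 6294. Genotypes gave 1181 to 3018 on day 0, 830 to 2758 on day 1, 911 to 2259 on day 2, 675 to 1605 on day 4 and 668 to 2592 for the mean. Differences in change gave 159 to 1451, 390 to 1690 and 421 to 2014. The highest count came without mouse 858 in every comparison but those of Mll1-deleted cultures over time. The correlation of day 4 changes ranged from 0.701 (without mouse 858) to 0.792, and 135 to 159 lists were called. Named calls ended numbered from 29 without mouse 858 to 191 without mouse 489. For the counts that rose without mouse 858, the cause was not tested.

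Leaving out a mouse or a day turned the direction of the test or of a gene in 4 results. Proliferation in Mll1-deleted cultures on day 1 had a median of -0.0392 without mouse 858 (adjusted p = 0.86, test up) and -0.797 without 814. Cholesterol synthesis there had -0.00983 (adjusted p = 0.998) and -0.381. Proliferation between genotypes on day 1 had -0.0369 without mouse 814 (adjusted p = 0.622) and 0.7 without 858. Camk2b in the mean over days was at 0.032 without day 0 (adjusted p = 0.899). Medians of lists also changed sign, without a turn of the test, for neuroblasts between genotypes on day 4 (from -0.185 to 0.0361 without mouse 489, adjusted p = 0.67) and for the oligodendrocyte lineage on day 2 (from 0.0858 to -0.0148 without mouse 858, adjusted p = 0.369). The cause was not tested. Intensities near the floor, the lowest being 3.48, limit what can be seen of genes with little expression.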

Other observations

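The test of Y-linked genes and the comparison of mouse 858 with wild-type mice left out in the same way were chosen only after the result was seen, and the bound of the first was changed after its value was known.

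Some of the largest differences lay outside the lists on neurons and glia. Matn2, a matrix protein, was higher in Mll1-deleted cultures by 3.49 ± 0.25 on day 1, 3.17 ± 0.25 on day 4 and 2.84 ± 0.21 in the mean over days. Spp1, a secreted phosphoprotein, was at 3.70 ± 0.53 on day 1 and 3.99 ± 0.53 on day 4, and the metalloreductase Steap4 at 3.98 ± 0.67 and 4.27 ± 0.67. The cytochrome gene Cyp2d22 was lower, at -3.09 ± 0.19 on day 2, -3.12 ± 0.19 on day 4 and -2.61 ± 0.15 in the mean. Slc6a11, a GABA transporter, was at -3.42 ± 0.19 on day 0 and -2.35 ± 0.10 in the mean, and the cystine transporter Slc7a11 at -2.77 ± 0.40 on day 4. Gap43, a growth cone protein that does belong to the neuroblast list, was higher on day 4 by 1.73 ± 0.21. The median of that list on day 4 was -0.185. These calls of limma rest on 3 mice per genotype and held in every alternative run.

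In wild-type cultures Angpt2, a ligand of vessel growth, and Igfbp3 fell by day 1, at -4.09 ± 0.21 and -4.14 ± 0.44. In Mll1-deleted cultures Lrrn1 and Smoc1 rose by 3.90 ± 0.21 and 3.70 ± 0.24 on day 1, and Cyp24a1, which breaks down vitamin D, was at -3.44 ± 0.29.

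For the other comparisons, splits of 6 samples (10 each) are also too few for a share under 0.05. In every one, 1 split, the real one, gave as many genes. Genotypes gave 2132, 1570, 1842 and 1361 genes on days 0, 1, 2 and 4 and 1539 for the mean, against 257 at most in another split on day 1, which set mouse 858 with 2 wild-type mice, and 3 elsewhere. Over time the real counts were 5363, 7095 and 7905 in wild-type and 2610, 4916 and 6231 in Mll1-deleted cultures. Among the 4 splits that part all 3 pairs of arrays, the highest but for the real one was 0, or 1 for Mll1-deleted day 4, and splits that keep a pair together reached 314 on Mll1-deleted day 1 and 1 at most elsewhere.

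Mouse 858 stood apart from the other Mll1-deleted mice. The planned test did not decide whether it is a wild-type mouse under a wrong label or placed in the group. At 2592 genes called without it, mouse 858 lay nearer the other Mll1-deleted mice in 52.8%. That is above the bound set for a wrong label but short of the 80% set against it. The share was 48.1 percentage points above the highest wild-type mouse (3.59 to 4.76%), while mice 489 and 814 were at 92.2 and 92.0%. Each of these mice was scored on other genes (668 to 948), called with mouse 858 in its group. Their shares are therefore not like for like with that of mouse 858. Splits that set a wild-type mouse in its place, beside mice 489 and 814, are like for like. With mouse 818, 862 or 870 there, they called 3, 0 and 1 genes on day 0, against 2132 with mouse 858. On day 1 they called 257, 0 and 0, against 1570. At most 3 were called on days 2 and 4, against 1842 and 1361. These counts argue against a wild-type mouse, though this use of the splits was not planned. A male animal stays open, since the largest difference of a Y-linked gene from the other mice was 0.0982 (log2) but no array here shows that these probe sets respond. Its cells may hold 1 X chromosome, since Xist was at 19.8 against 522 to 905 in the others and 3 genes that escape inactivation, Kdm5c, Kdm6a and Ddx3x, were all below every other mouse with a median difference of -0.342, and an incomplete deletion stays open as untested, as the Kmt2a probe set does not report it.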
